A study of Mus musculus with 6 samples.

How the data were processed

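RNA of SV40 MES 13 mouse mesangial cells was captured on oligo(dT) beads and sequenced as paired reads of 150 bp on an Illumina instrument, per the labels' protocols. The authors deposited 1 table of raw counts per gene, with a gene length, a symbol and a biotype for each gene, per the file headers. Trim Galore, HISAT2, featureCounts and DESeq2 are named with the mouse build mm10 (GRCm38), per the submitters' processing notes, without versions. Their settings, the annotation release and whether counting used strand are not given in the sources used here, so reads from overlapping antisense genes, and reads shared between a gene and its near copies, cannot be told apart in these counts. No values normalized by the authors were used.

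Libraries were assigned to the 3 Dlx6os1 shRNA and 3 negative control shRNA samples by the names of the table's columns and the sample titles. The table has 20623 gene lines. For 1 gene, Ttn, the record was broken over a pair of lines, so these 2 lines were left out, and 20621 genes with whole-number counts in every library remained. The table of gene names matched 20497 of them. Coordinates, biotypes and GC content were taken from GENCODE M21 on GRCm38. Total counts per library ranged from 33557306 to 48965117, and 3 counts, the limit that a count of 0 allows, correspond to between 0.061 and 0.089 CPM. Such limits cover counting error only, since reads copied by PCR are not independent molecules. The lowest chi-square per degree of freedom between a pair of libraries of a group was 228, so no library was a copy of another within sampling noise.

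The main test was edgeR 4.0.16's quasi-likelihood test in R 4.3.3 on the deposited counts, with TMM normalization, filterByExpr (minimum count 10) and group as the only term. It kept 14837 genes, which held 99.96% of the counts. A positive log2 fold change means higher with Dlx6os1 shRNA. Standard errors of log2 fold changes were derived from the F statistic. The p-values were adjusted by the method of Benjamini and Hochberg over all tested genes, with a limit of 0.05, and, for each list fixed before the data were examined, again over the list alone. The adjustment over a list alone does not cover the number of lists, and 8 lists held a gene that passed it. The 40 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, with adjustment over the 39 lists that had at least 2 tested genes. CPM, counts scaled to a common library size, was computed with TMM-adjusted library sizes.

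Genes named in the text were to be Dlx6os1, Dlx5 and Dlx6, then the 10 largest rises and 10 largest falls with an adjusted p under 0.05, at least 2 CPM in the higher group and no overlap between groups. Next came the 5 smallest p-values in each direction with an adjusted p under 0.05, and up to 4 members with the smallest p of each list that passed in camera or had at least 3 called genes. Names of clone type were skipped in the parts on size and on p. The part on lists gave 16 genes, of which 1 is not reported here. The others named were chosen after their values were seen: the 10 smallest p-values of genes with at least 2 CPM in the higher group and no name of clone type, the smallest p-values in lists of apoptosis, inflammation and cell markers, and well-known members named for contrast.

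The alternatives were RLE normalization, library totals, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom without and with sample quality weights, a replicate block, leaving out each library in turn, and leaving out mitochondrially encoded genes with the 10 most abundant genes. For lists they also included an estimated correlation and the rotation test fry. The fits were tested on simulated counts. With 14837 genes simulated for this comparison, 10 of 14579 unchanged genes were called, both lists shifted by 0.4 on the log2 scale were called, and 0 of the 37 other lists were. The genes were drawn independently, so the simulation could not show false list calls that correlated members would cause. Each named gene's longest transcript was compared with all M21 transcripts by BLASTN 2.17.0.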

Results

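Poly(A)-selected RNA was sequenced from SV40 MES 13 cells, a mouse glomerular mesangial cell line, kept in 30 mmol/L glucose for 96 h as a cell model of diabetic nephropathy. The cells had been transfected with a plasmid for a short hairpin RNA (shRNA) against the long non-coding RNA Dlx6os1 in 3 libraries or with a negative control shRNA in 3 libraries. The reads were paired, 150 bp long. Total gene counts ranged from 33557306 to 47979232 in the Dlx6os1 shRNA libraries and from 42314620 to 48965117 in the negative control libraries. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Nor do they say whether the number in a library's name stands for a replicate or for a different hairpin.

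The targeted transcript could not be used to check the labels. Dlx6os1 (ENSMUSG00000090063) is annotated in GRCm38 as an antisense gene on the minus strand of chromosome 6, from 6820189 to 6871592, where it overlaps Dlx6 (6863334 to 6868568, plus strand) and lies next to Dlx5 (6877805 to 6882085, minus strand). The table used here has 0 rows for Dlx6os1, 0 for Dlx6 and 0 for Dlx5, so their levels are not analysed here and the depth of the knockdown is not known. Every direction below therefore rests on the names of the table's columns.

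The comparison asks which mRNAs differ when Dlx6os1 is targeted in high glucose, with apoptosis and inflammation as the study's stated interest. Genes of cholesterol and fatty acid synthesis rose as a set with Dlx6os1 shRNA. Of the 31 measured members 28 had a higher and 3 a lower estimate, and the median log2 fold change was 0.44 (interquartile range 0.19 to 0.74). Hmgcs1, the cytosolic HMG-CoA synthase, stood at 200.2 ± 34.8 CPM (counts scaled to a common library size; SD, n = 3) against 119.7 ± 7.17 CPM in the control, a log2 fold change of 0.74 ± 0.34 (SE). Lss, the lanosterol synthase, had a log2 fold change of 0.93 ± 0.39 (SE) and Cyp51, the lanosterol demethylase, 0.92 ± 0.41 (SE). None of these 3 genes passed on its own in edgeR's quasi-likelihood test (adjusted p from 0.541 to 0.599), and 0 of the 31 passed when adjusted over the list alone. The set's adjusted p was 0.00078 in camera with a preset correlation. It was 0.322 with an estimated correlation (camera adjusted p) and 0.0097 in the rotation test fry, which asks whether the members move one way without comparing them with other genes. The estimated correlation was -0.025, below the preset 0.01, so correlated members do not account for the larger value. With an estimated correlation camera also takes its degrees of freedom from the libraries and not from the genes, so the settings differ in more than the correlation.

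The NRF2 and oxidative stress genes were the second set that rose. Of 29 measured members 24 had higher and 5 lower estimates, with a median log2 fold change of 0.27 and a camera adjusted p of 0.032, which was 0.407 with an estimated correlation. Pgd, an NADPH-producing enzyme of the pentose phosphate pathway, stood at 209 ± 13.2 CPM against 81.7 ± 37.1 CPM (SD, n = 3 each), a log2 fold change of 1.35 ± 0.41 (SE). G6pdx, the first enzyme of that pathway, had a log2 fold change of 0.88 ± 0.48 (SE), Hmox1, the heme oxygenase, 0.85 ± 0.40 (SE), and Sod1, the cytosolic superoxide dismutase, 0.83 ± 0.42 (SE). The G6pdx transcript matches G6pd2 with 93.2% identity over 87.9% of its length, so its counts are uncertain. Nqo1, a standard NRF2 target, had 0.21 ± 0.41 (SE), and Sod2, the mitochondrial superoxide dismutase, 0.06 ± 0.38 (SE). No member passed on its own over all genes or when adjusted over the list alone (0 of 29 each). The set's adjusted p was 0.211 in fry, 0.084 in camera without Dlx6os1 shRNA replicate 3 and 0.144 without control replicate 1.

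Interferon-stimulated genes fell as a set. Of 39 measured members 28 had lower and 11 higher estimates, with a median log2 fold change of -0.27 and a camera adjusted p of 0.035, which was 0.407 with an estimated correlation. Mx2, an interferon-induced dynamin-like GTPase annotated as a polymorphic pseudogene in this mouse reference, stood at 0.78 ± 0.11 CPM against 2.53 ± 0.37 CPM in the control (SD, n = 3 each), a log2 fold change of -1.70 ± 0.36 (SE). It was the 1 member that passed when adjusted over the list alone, and did not pass over all genes (adjusted p = 0.165, edgeR). Its mean of 74.8 counts lay under 100 counts, where small p-values were more frequent among all genes. Its transcript matches Mx1 with 94.8% identity over 37.2% of its length, so its counts are uncertain. Iigp1, an interferon-inducible GTPase, had -1.66 ± 0.46 (SE), Rsad2, which encodes viperin, -1.23 ± 0.40 (SE), and Isg20, an exonuclease, -1.01 ± 0.40 (SE). Iigp1 was weakly expressed, at 0.21 CPM against 0.70 CPM in the control, and a pseudogene matches its transcript with 88.2% identity over 39.2% of its length. Ifit1 at -0.14 ± 0.38 (SE) differed by less than its error. The set's adjusted p was 0.078 in fry, while fry's mixed test, for changes in either direction, gave 0.00033. Camera's adjusted p was 0.086, 0.059 and 0.068 without Dlx6os1 shRNA replicates 1, 2 and 3 and 0.144 without control replicate 1.

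Mitochondrially encoded mRNAs were the last of the 4 sets called, and their members were uneven. The median log2 fold change of the 13 mRNAs was 0.44, 9 had higher and 4 lower estimates, and the camera adjusted p was 0.038, or 0.407 with an estimated correlation. mt-Nd2, a complex I subunit, stood at 1706 ± 394 CPM against 645 ± 162 CPM (SD, n = 3 each), a log2 fold change of 1.40 ± 0.36 (SE), and was the 1 member that passed when adjusted over the list alone (adjusted p = 0.207 over all genes, edgeR). mt-Co3, a subunit of cytochrome c oxidase, had 0.88 ± 0.37 (SE), mt-Nd4l 0.88 ± 0.47 (SE) and mt-Nd3 0.75 ± 0.36 (SE). mt-Co1 at -0.55 ± 0.43 (SE) and mt-Atp6 at -0.28 ± 0.34 (SE) lay on the other side of 0. Pseudogene copies in the nuclear genome match mt-Co3, mt-Nd4l, mt-Nd3 and mt-Atp6 with at least 99.7% identity over at least 99.0% of their length, mt-Co1 with 97.6% over its whole length and mt-Nd2 with 96.7% over 49.1% of its length, so the counts of all 6 are uncertain. The nuclear genes of the same respiratory chain did not pass as a set (29 measured, 11 higher and 18 lower, adjusted p = 0.875). The mitochondrial set's adjusted p was 0.105 in fry. In camera it was 0.087, 0.105 and 0.068 without Dlx6os1 shRNA replicates 1, 2 and 3 and 0.144 without control replicate 1. In cameraPR, the form of camera that takes moderated t values, it went from 0.032 to 0.264 once their trend with GC content and length was removed.

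**Figure D1:**
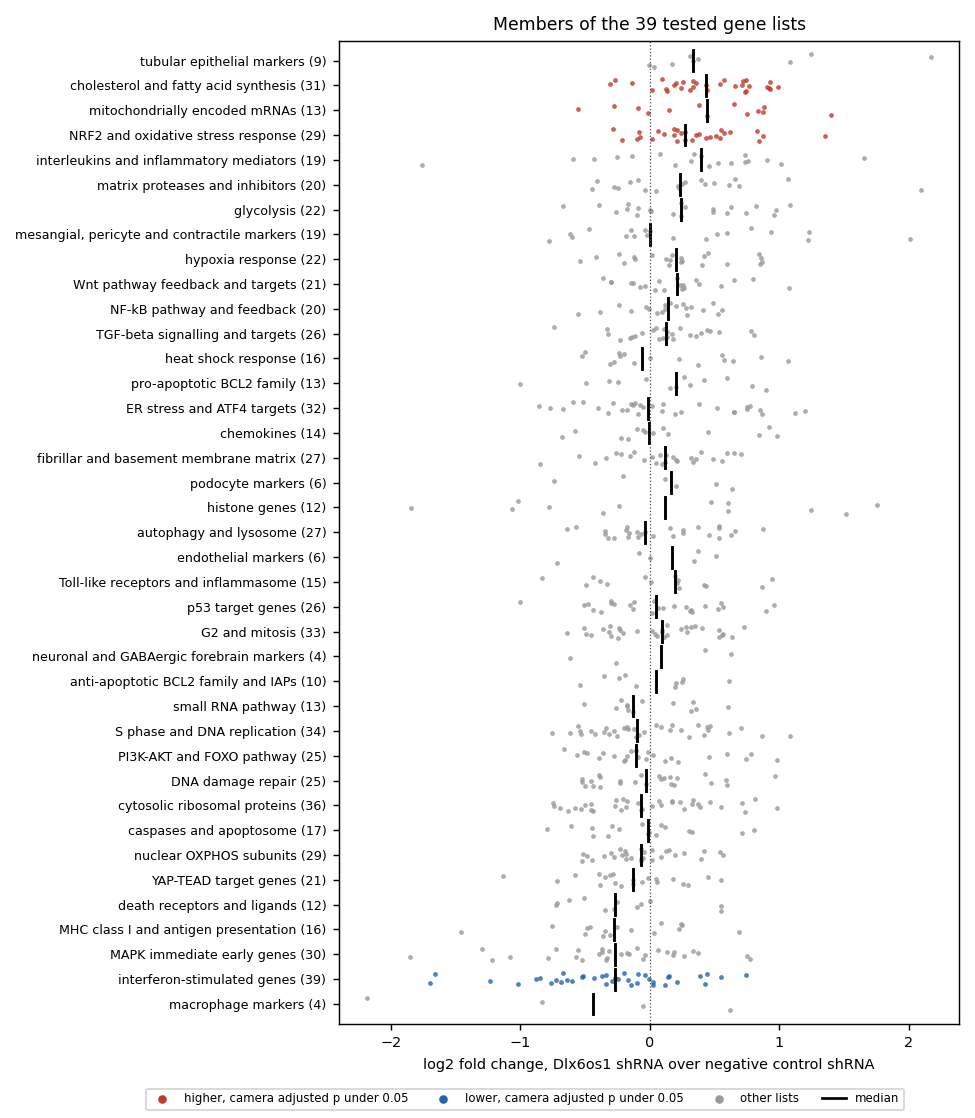
Each point is a measured gene, placed by its log2 fold change of Dlx6os1 shRNA over negative control shRNA (horizontal axis) within its gene list (vertical axis, number of measured genes in brackets), and black bars are list medians. The medians of the 4 lists called by camera are 0.44, 0.44 and 0.27 for the red lists and -0.27 for the blue list. Members lie on both sides of 0 in the called lists and in the other lists alike.

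One single gene passed over all 14837 genes tested. Gm13339 (ENSMUSG00000082884), an unprocessed pseudogene on chromosome 2 from 22590024 to 22590533 (GRCm38, minus strand, inside the span of Myo3a on the opposite strand), stood at 6.15 ± 0.32 CPM with Dlx6os1 shRNA against 0.68 ± 0.12 CPM in the control (SD, n = 3 each). The log2 fold change was 3.16 ± 0.38 (SE) and the adjusted p 0.023 (edgeR). It lies outside the rule for named genes and was chosen after its values were seen. Its 510-base transcript matches mt-Nd2 over its whole length with 96.7% identity, so reads of mt-Nd2 may be counted in it and its value is uncertain as a measure of its own transcription. A fixed share of mt-Nd2 reads would carry the 2.64-fold change of mt-Nd2, whereas Gm13339 changed 8.96-fold, and the source of its reads was not tested. The count of called genes was 1 higher and 0 lower by edgeR at a false discovery rate of 0.05, with 602 higher and 619 lower at an unadjusted p under 0.05. DESeq2, run without the low-count filter on 20613 genes, called 17 (9 higher and 8 lower), and limma-voom called 5 (2 higher and 3 lower). Without any 1 of the 6 libraries, edgeR called 0 genes, with 1177 to 1265 at an unadjusted p under 0.05.

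Because nothing passed the rule for the largest changes, the genes below were chosen after their values were seen, as those with the smallest p among genes of at least 2 CPM in the higher group, with names of clone type left out. Gm44126, one of those left out, had a lower adjusted p (0.086, edgeR) than any of them. None of them passed in edgeR (adjusted p from 0.096 to 0.175). Tagln, the actin-binding protein transgelin, stood at 155 ± 32.1 CPM against 38.3 ± 17.3 CPM (SD, n = 3 each), a log2 fold change of 2.02 ± 0.44 (SE). Krt7, a keratin of simple epithelia, had 135 ± 11.2 CPM against 40.2 ± 17.2 CPM and a log2 fold change of 1.75 ± 0.39 (SE). Ramp2, a subunit of the adrenomedullin receptor, had a log2 fold change of 2.08 ± 0.43 (SE), and its annotated span overlaps Vps25 on the same strand. The Ramp2 transcript matches Vps25 with 100% identity over 74.6% of its length, so its counts are uncertain. Sult1c2, a cytosolic sulfotransferase, had 1.78 ± 0.39 (SE), and St8sia1, the ganglioside GD3 synthase, 1.71 ± 0.39 (SE). Lmbr1l at -2.20 ± 0.49 (SE), or -2.91 without Dlx6os1 shRNA replicate 1, and Ddx43, a helicase gene, at -1.72 ± 0.35 (SE) had lower estimates. Tagln, Krt7, Ramp2, Sult1c2, Lmbr1l and Ddx43 were among the 17 genes of DESeq2, whose adjusted p was 0.018 for Tagln and 0.034 for Krt7. A pair of the smallest p-values belonged to features that share sequence with abundant mRNAs and are uncertain. Rps27a-ps2 (-1.95 ± 0.36, SE) matches Rps27a with 99.8% identity over its whole length while Rps27a itself had 0.82 ± 0.38 (SE), and Mir703 (1.71 ± 0.37, SE) matches Eef1a1 with 98.2% identity.

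**Figure D2:**
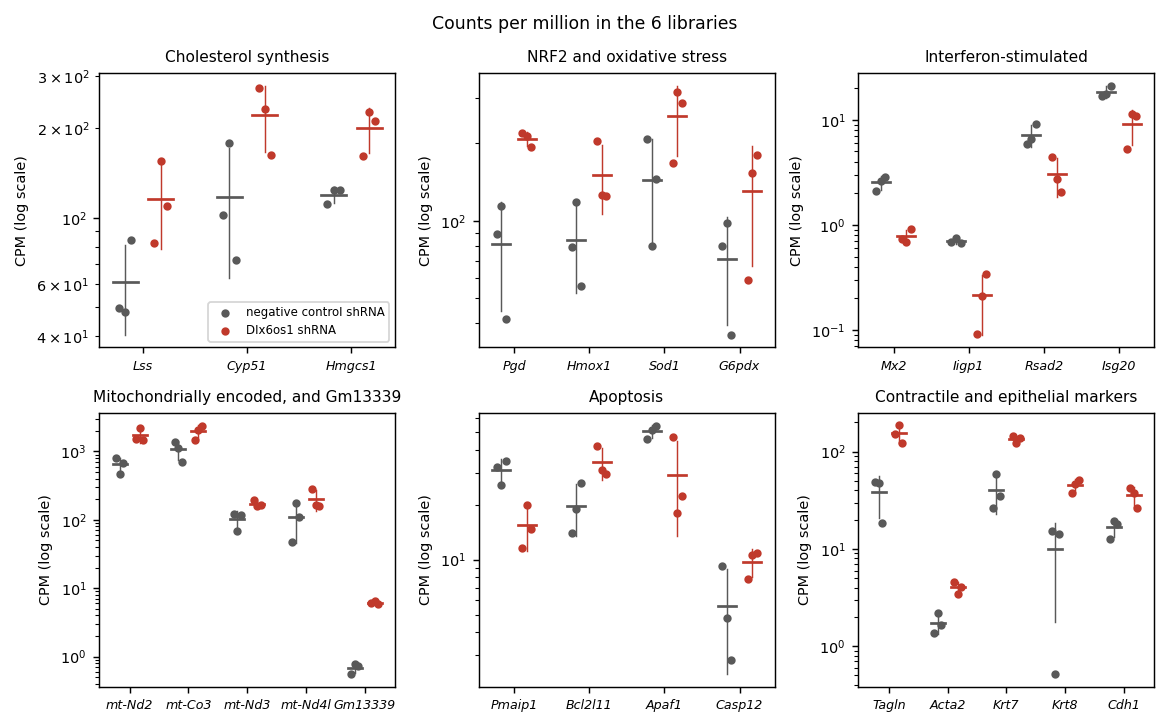
Points are the CPM of the 3 negative control (grey) and 3 Dlx6os1 shRNA (red) libraries on log axes for genes named in the text, horizontal bars are means and vertical bars 1 SD. For Gm13339, Tagln, Krt7 and mt-Nd2 the groups do not overlap, with log2 fold changes of 3.16, 2.02, 1.75 and 1.40.

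Genes of apoptosis, which the study set out to examine, did not pass as sets. The proapoptotic BCL2 family had 8 higher and 5 lower members of 13 measured (camera adjusted p = 0.883). Pmaip1, which encodes the proapoptotic protein NOXA, stood at 15.4 ± 4.28 CPM against 30.9 ± 4.59 CPM (SD, n = 3 each), 2.01-fold lower, and did not pass (adjusted p = 0.449, edgeR). Bcl2l11, which encodes BIM, had the opposite sign, with 0.79 ± 0.38 (SE). The antiapoptotic BCL2 family and inhibitors of apoptosis had 5 higher and 5 lower members of 10 (adjusted p = 0.997), with Birc2 at 0.61 ± 0.37 (SE) and Bcl2l2 at -0.54 ± 0.35 (SE). Caspases and apoptosome components had 7 higher and 10 lower members of 17 (adjusted p = 0.883). Among them Apaf1, the apoptosome scaffold, had -0.79 ± 0.41 (SE) and Casp12 0.80 ± 0.44 (SE). Death receptors and their ligands had 3 higher and 9 lower members of 12 (adjusted p = 0.426), with Tnfrsf21 at 0.55 ± 0.35 (SE) and Tnfrsf25 at -0.73 ± 0.44 (SE). The p53 target genes had 15 higher and 11 lower members of 26 (adjusted p = 0.883), with Eda2r at 0.57 ± 0.36 (SE). In these 5 lists 0 genes passed over all genes and 0 when adjusted over each list alone.

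Genes of inflammation went different ways and did not pass as sets in the main test. Interleukins and inflammatory mediators had 14 higher and 5 lower members of 19, with a median log2 fold change of 0.39 and a camera adjusted p of 0.094. The value was 0.0033 among genes with at least 1 CPM in at least 3 libraries, 0.407 with an estimated correlation, 0.211 in fry, 0.149 with a replicate block and 0.099 to 0.342 without 1 library. Saa3, an acute-phase serum amyloid, stood at 3.70 ± 0.82 CPM against 1.18 ± 0.44 CPM (SD, n = 3 each), a log2 fold change of 1.66 ± 0.40 (SE), and was the 1 member that passed when adjusted over the list alone (adjusted p = 0.199 over all genes, edgeR). Il15, weakly expressed at 0.41 CPM against 1.35 CPM, had -1.76 ± 0.58 (SE), or -2.66 without Dlx6os1 shRNA replicate 1. Csf1, the macrophage growth factor, had 0.73 ± 0.43 (SE). Chemokines had 7 higher and 7 lower members of 14 (adjusted p = 0.838), with Cx3cl1 at 0.92 ± 0.41 (SE), Ccl17 at 0.98 ± 0.42 (SE) and Ccl2 at -0.17 ± 0.42 (SE). Ccl17 was weakly expressed, at 0.88 CPM against 0.44 CPM in the control. The NF-kB pathway and its feedback genes had 14 higher and 6 lower members of 20 (adjusted p = 0.391), with Nfkb2 at 0.53 ± 0.46 (SE) and Rela at -0.56 ± 0.49 (SE). Toll-like receptors and inflammasome genes had 9 higher and 6 lower members of 15 (adjusted p = 0.838). The genes of MHC class I and antigen presentation had 6 higher and 10 lower members of 16 (adjusted p = 0.159). There Tap2, a subunit of the peptide transporter, stood at 48.7 ± 11.5 CPM against 134 ± 26.0 CPM, with -1.46 ± 0.37 (SE), and was the 1 member that passed when adjusted over the list alone (adjusted p = 0.207 over all genes, edgeR). H2-Q4, one of a family of near copies and so uncertain, had -0.76 ± 0.35 (SE).

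Markers of mesangial cells and of other kidney cells were compared to see whether the cell state or the makeup of the cultures differed. The mesangial, pericyte and contractile markers had 10 higher and 9 lower members of 19 (camera adjusted p = 0.225), while fry's mixed test gave 0.0029. A pair of these genes, Tagln and Acta2, the smooth muscle actin, passed when adjusted over the list alone, and Acta2 stood at 4.05 ± 0.57 CPM against 1.73 ± 0.41 CPM (log2 fold change 1.23 ± 0.37, SE). Desmin (Des) had -0.12 ± 0.38 (SE) and Myl9, a myosin light chain, -0.60 ± 0.36 (SE). The tubular epithelial markers had 8 higher and 1 lower of 9 measured, with a camera adjusted p of 0.060. The value was 0.031 without control replicate 3, 0.049 with a replicate block, 0.204 without control replicate 2, 0.12003 among genes with at least 1 CPM in at least 3 libraries, 0.328 in fry and 0.407 with an estimated correlation. Krt8 stood at 45.3 ± 6.67 CPM against 10.0 ± 8.25 CPM and Cdh1, which encodes E-cadherin, at 35.5 ± 8.28 CPM against 16.7 ± 3.55 CPM (SD, n = 3 each), with log2 fold changes of 2.18 ± 0.79 (SE) and 1.09 ± 0.38 (SE), and neither passed over all genes (adjusted p = 0.430 and 0.392, edgeR). For Krt8 control replicate 2 stood at 0.51 CPM, against 15.2 and 14.4 CPM in the other control libraries. A pseudogene copy matches Krt8 with 98.6% identity over 48.1% of its length, so its counts are uncertain. Krt18, the partner keratin of Krt8, had 0.31 ± 0.43 (SE), and Epcam 0.34 ± 0.39 (SE). Counts of Krt18 are uncertain too, since a pseudogene matches it with 90.45% identity over 88.2% of its length. Podocyte markers had 6 measured genes and endothelial markers 6 (adjusted p = 0.838 and 0.883). Macrophage markers had 4, with 1 passing when adjusted over the list alone (set adjusted p = 0.308), and neuronal and GABAergic forebrain markers had 4 (adjusted p = 0.997). Of the lymphocyte markers 1 of 11 was measured, and no test was made.

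At this spread, single-gene tests could show only large changes. In counts simulated with the means, depths and dispersions of these libraries, the edgeR test called 1 of 68 genes given a 2-fold change, 44 of 66 given a 4-fold change and 66 of 66 given an 8-fold change, among 14837 genes. The changed genes had a mean of at least 20 counts and were simulated together. With many true changes the limit on the adjusted p is easier to pass, so with fewer large changes these shares would be lower. The biological coefficient of variation was 0.378. Library profiles correlated at 0.957 to 0.960 within groups and 0.950 to 0.953 between them (Pearson's r of log2 CPM, across genes, which are not independent replicates). The first principal component, with 26.5% of the variance, parted the groups. The groups did not overlap for 2310 genes, 15.6% of those tested, where chance gives 10%. Group differences lay mainly in weakly expressed genes: 647 of 3064 genes with a mean under 100 counts (21.1%) had an unadjusted p under 0.05 against 574 of 11773 (4.88%) with more. The 4.88% is about what a p limit of 0.05 gives by chance. The other 9 splits of the 6 libraries into groups of 3 gave 55 to 86 such genes under 100 counts and 336 to 387 with more. Those splits mix the real groups, so a group difference adds to their spread and lowers their counts.

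**Figure D3:**
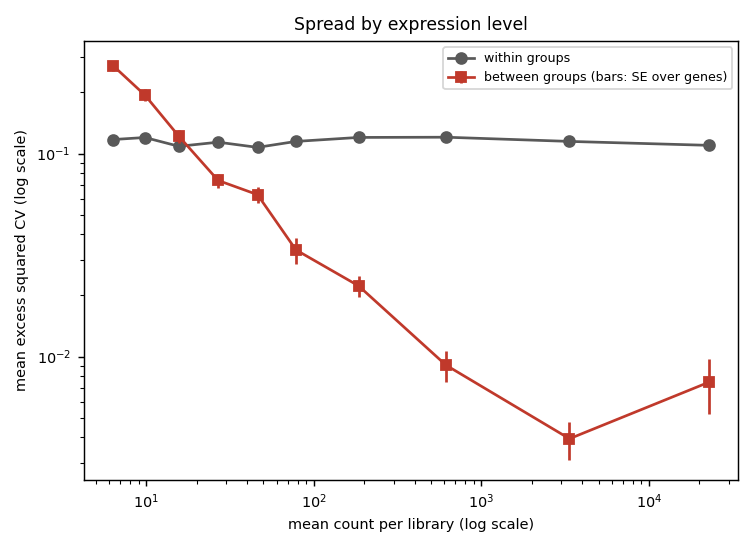
Mean excess squared coefficient of variation (vertical log axis, no unit) against mean count per library (horizontal log axis) in 10 ranges of genes, within groups (grey circles) and between groups (red squares, bars are SE over genes). Within groups it is 0.117 at 5 to 8 counts and 0.110 above 10000 counts, while between groups it goes from 0.270 at 5 to 8 counts to 0.00394 at 1000 to 10000 counts and is 0.00747 above 10000 counts.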

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

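Counting genes at an unadjusted p, the false discovery rate of 0.10, the removal of the GC content and length trend and the restriction to genes of at least 1000 counts were chosen after seeing the data; the other settings were fixed before the data were examined. The count of 1 called gene, and of 1 changed at least 2-fold, was within 1.5 times under RLE normalization, library totals, the filter of at least 1 CPM in at least 3 libraries and without mitochondrial and the 10 most abundant genes. For both counts the value was 21 with no low-count filter, 17 with DESeq2, 5 with limma-voom, 5 with quality weights and 20 at a false discovery rate of 0.10, and 0 without any 1 of the 6 libraries (1177 to 1265 genes at an unadjusted p under 0.05). DESeq2 was run without the low-count filter, on 20613 genes, so the method and the filter changed together. The labels do not say whether the numbers pair the samples. The deviations of same-numbered libraries showed no shared pattern (correlations of -0.010, -0.007 and -0.008), which does not settle how they were prepared. With the replicate block 0 genes were called (1145 at an unadjusted p under 0.05). Of the genes at an unadjusted p under 0.05 there were 1221 in the main fit, 2347 with no filter and 710 with at least 1 CPM, where fewer genes were tested. Of the 65 genes followed, 58 kept the sign of their log2 fold change in every setting that tested them. The other 7, all small, turned only without 1 library, with ranges of -0.035 to 0.56 for Nqo1, -0.20 to 0.33 for Sod2, -0.30 to 0.13 for Ifit1, -0.53 to 0.072 for Ccl2, -0.36 to 0.090 for Des, -0.77 to 0.080 for Fos and -0.17 to 0.52 for Hk2. The fold moved by over 1.5 times for Lmbr1l (-2.91) and Il15 (-2.66) without Dlx6os1 shRNA replicate 1 and for Egr3 (-2.51) without Dlx6os1 shRNA replicate 3. Ranges without 1 library were also wide for Nfkb2 (0.019 to 0.83) and Rela (-0.99 to -0.11).

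The number of lists called was 4, against 0 with an estimated correlation, 1 with fry and 1 to 5 without 1 library. Adjusted p with an estimated correlation was 0.322 for cholesterol and fatty acid synthesis and 0.407 for the NRF2, interferon and mitochondrial lists. The correlation estimates were -0.025, 0.026, -0.0068 and -0.033 in that order, and only that of NRF2 lay above the preset 0.01. That setting also lowers the degrees of freedom of the test, so its larger values do not measure correlation alone. Fry gave 0.211, 0.078 and 0.105 for the NRF2, interferon and mitochondrial lists. Without 1 library the ranges were 0.0091 to 0.144 (NRF2), 0.031 to 0.144 (interferon), 0.031 to 0.144 (mitochondrial) and 0.031 to 0.204 (tubular epithelial markers). Cholesterol and fatty acid synthesis was called under RLE normalization, library totals, the filter of at least 1 CPM, the replicate block, fry, the removed trend, at least 1000 counts and without each of the 6 libraries (0.0014 to 0.0056), but not with the estimated correlation. The lists were not run with no low-count filter, DESeq2, limma-voom as a gene test or without mitochondrial and the 10 most abundant genes. In cameraPR on moderated t values the mitochondrial list had 0.032 before and 0.264 after the trend was removed. In camera the interferon list had 0.157 among genes of at least 1000 counts, where 12 of its 39 genes were tested. The median log2 fold change of these 12 was -0.35, against -0.27 for all 39. Lists newly called were interleukins with at least 1 CPM (0.0033) and tubular epithelial markers with the replicate block (0.049) and without control replicate 3 (0.031).

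Directions turned only in lists that were not called. They turned for the antiapoptotic list with at least 1 CPM (0.997), library totals (0.981), the block (0.966) and at least 1000 counts (0.574), for histones (0.722) and neuronal markers (0.896) with at least 1 CPM, for S phase with the block (0.945) and at least 1000 counts (0.962), and at least 1000 counts for p53 targets (0.574) and the small RNA pathway (0.992). Without 1 library adjusted p ranged from 0.752 to 0.995 for DNA damage repair, 0.825 to 0.995 for PI3K-AKT, caspases and the proapoptotic list, 0.808 to 0.926 for S phase, 0.428 to 0.967 for Toll-like receptors, 0.862 to 0.967 for the antiapoptotic list, 0.522 to 0.958 for ribosomal proteins, 0.603 to 0.995 for endothelial markers, 0.877 to 0.995 for histones, 0.825 to 0.958 for neuronal markers, 0.582 to 0.967 for p53 targets, 0.7002 to 0.915 for podocyte markers and 0.879 to 0.995 for the small RNA pathway, each with a turn in at least 1 of the 6 fits. The cause of these changes was not tested.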

Other observations

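Other lists were measured that the comparison above did not describe. The MAPK immediate early genes had 21 lower and 9 higher estimates among 30 (camera adjusted p = 0.094). Egr1, a growth factor-induced transcription factor, stood at 331 CPM against 702 CPM in the control, with a log2 fold change of -1.08 ± 0.37 (SE). Fosb had -1.22 ± 0.38 (SE) and Fos -0.34 ± 0.53 (SE). Egr3, near the detection limit at 0.098 CPM against 0.37 CPM, had -1.85 ± 0.52 (SE), or -2.51 without Dlx6os1 shRNA replicate 3. None of them passed over all genes in edgeR (adjusted p = 0.373 for Egr1). Glycolysis genes had 15 higher and 7 lower estimates among 22 (adjusted p = 0.094), with Pfkl at 0.60 ± 0.34 (SE) and Hk2 at 0.18 ± 0.45 (SE), and hypoxia genes 16 higher and 6 lower among 22 (adjusted p = 0.161). Matrix proteases and inhibitors had 13 higher and 7 lower among 20 (adjusted p = 0.196), with Mmp10, a stromelysin near the detection limit at 0.36 CPM against 0.08 CPM, as the 1 gene that passed when adjusted over the list alone. Cell cycle lists did not pass, with 15 of 34 S phase genes higher (adjusted p = 0.997), 20 of 33 G2 and mitosis genes higher (0.875) and 12 of 25 DNA damage repair genes higher (0.988).

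Fibrillar and basement membrane matrix genes had 18 higher and 9 lower estimates among 27 (camera adjusted p = 0.690), and TGF-beta signalling 18 higher and 8 lower among 26 (0.618). The adjusted p was 0.310 for YAP-TEAD targets, 0.329 for Wnt targets, 0.626 for ER stress and ATF4 targets, 0.838 for the heat shock response, 0.838 for autophagy and lysosome, 0.891 for PI3K-AKT and FOXO, 0.997 for the small RNA pathway and 0.883 for cytosolic ribosomal proteins. Histone genes had 6 higher and 6 lower estimates among 12 (0.883), yet fry's mixed test gave 1.4e-05 and 2 of them passed when adjusted over the list alone. Of these 12 genes, 5 had a mean of at least 100 counts. Among all tested genes with a mean under 100 counts, 21.1% had an unadjusted p under 0.05 (edgeR). Fry does not compare members with other genes, so its mixed result may not be particular to histones. The sign of the median and the direction of the camera test differed in 6 lists and that of the mean in 0, none of them among the 4 called lists. Fry's mixed test called 7 lists in all, among them ER stress with 0.018 and MHC class I with 0.032.

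In the paragraphs that follow, the tests of library preparation, of shared gene programs, of the level dependence of the group differences, of matched nuclear genes, of the size of shared counting noise in the lists and of other splits were chosen after the results were seen. Their bootstrap intervals resample genes or lists with the libraries held fixed, so they do not cover the spread between libraries. The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split called 1 gene, which differed at least 2-fold, had 1221 genes at an unadjusted p under 0.05 and called 4 lists. The highest values among the other 9 splits were 0, 0, 473 and 0, so in each case 1 of the 10 splits reached the real value. These 9 splits mix the real groups, so a group difference adds to their spread and lowers their counts. Chance would give about 742 genes at an unadjusted p under 0.05.

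The spread within groups had about one relative size in the 10 ranges of expression and was, on average, not shared between the genes of a list. Beyond counting noise, the squared coefficient of variation within groups was 0.117 for genes of 5 to 8 counts, 0.114 for 20 to 35 counts and 0.110 above 10000 counts. Few starting molecules in library preparation would make it fall with expression, but the ratio of the highest level to 20 to 35 counts was 0.965 (95% bootstrap interval 0.877 to 1.05). Shared gene programs that differ between cultures are argued against by a mean correlation of deviations within lists of 0.00161 (interval -0.0162 to 0.0194, 35 lists). Single lists ranged from -0.22 (histones, 5 genes) to 0.15 (Toll-like receptors, 12 genes), and 2 lists, the latter and the tubular epithelial markers (0.113), lay above the 0.1 taken as the mark of such programs. Of 100 random lists of the same size, 4 were as high as the Toll-like receptors and 12 as high as the tubular markers, while 1 was as high as the cytosolic ribosomal proteins (0.0431, 36 genes), so in single lists shared programs stay open. Trends with GC content and length took at most 0.108% of the variance of a library. Differences of single genes between cultures, and steps between reads and counts, stay open and may give such a spread.

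Differences between the groups beyond that spread lay mainly in low-count genes. Of the 3064 tested genes with a mean under 100 counts, 647 (21.1%) had an unadjusted p under 0.05, against 574 (4.88%) of the 11773 with more. The 4.88% is about what a p limit of 0.05 gives by chance. The other 9 splits gave 55 to 86 and 336 to 387. They mix the real groups, so a group difference lowers their counts, and for the genes with more counts this comparison cannot show a difference. At 1000 to 10000 counts the ratio of the variance between groups to that within them was 1.103. It was at most 1.025 in the other splits, which are lowered in the same way. The group term's excess squared coefficient of variation was 0.270 at 5 to 8 counts and 0.00394 at 1000 to 10000, with 0.00747 above 10000. The ratio of 1000 to 10000 counts to 5 to 8 counts, 0.0146 (interval 0.00846 to 0.0207), argues against a hairpin effect of one relative size at every level. The excess times the mean count was level between 5 to 8 and 20 to 35 counts, with a ratio of 1.13 (interval 0.933 to 1.36), which is consistent with counting noise that the 3 libraries of a group share, as if they had come from 1 common sample of molecules. Such noise alone would keep the product level, yet it rose from 1.69 at 5 to 8 counts to 2.89 at 35 to 60, 4.002 at 100 to 300, 11.1 at 1000 to 10000 and 203 above 10000. The ratio to 5 to 8 counts was 120 (interval 42.6 to 201) above 10000 counts, which argues against shared counting noise as the cause of the small differences there. At 1000 to 10000 counts it was 6.55 (interval 2.8 to 10.6), too wide an interval to decide. Genes at 0 in exactly 3 libraries went with shared noise at low counts: 112 were at 0 in the 3 Dlx6os1 shRNA libraries and 101 in the 3 controls, against 18 to 62 for each of the other 18 sets of 3; a hairpin effect that is larger in weakly expressed genes stays open and untested.

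The 4 called lists were weighed against a technical trend and shared counting noise. Removing the trend of the moderated t values with GC content and length left 3 of the 4 called, which argues against that trend as the cause of all 4. Counting noise shared by the 3 libraries of a group falls with the count and is independent between genes. At the level of 1.913 for the excess times the mean count, the highest found under 35 counts, the largest mean log2 fold change it would give in any of the 39 lists is 0.0725 times the mean of the cholesterol list (interval 0.0502 to 0.108), 0.101 times that of NRF2 (0.0596 to 0.176) and 0.0931 times that of the mitochondrial list (0.0242 to 0.353), which argues against such noise as the cause of these 3 shifts. The limit does not cover the larger product found at 1000 to 10000 counts (11.1) and above (203). Most members of these lists (29 of 31, 25 of 29 and 12 of 13) had at least 1000 counts. For the interferon list, with more weakly expressed members, it is 0.322 times (0.211 to 0.669). At that level such noise falls short of the whole shift but may give part of it, and how large a part cannot be told. Among genes of at least 1000 counts, where such noise is smallest, the median log2 fold change of 12 of its 39 members was -0.35, against -0.27 for all 39. The list's camera adjusted p there was 0.157, with fewer genes. For the mitochondrial list the mean moderated t went from 1.17 to 0.65 (SD over genes 1.57 before and after) and its adjusted p in cameraPR, which takes these t values, from 0.032 to 0.264, so the call ended because the mean shrank while the spread of its members stayed. Nuclear genes nearest to it in GC content and length had a median log2 fold change 0.221 times that of the list (interval -0.0779 to 0.535), too wide an interval to decide, so for this list such a trend and a change of the transcripts cannot be told apart. For the cholesterol, NRF2 and interferon lists an effect of the hairpin, on the target or off it, may underlie the shift and was not tested. The labels do not say whether the libraries of a group hold different hairpins, and no rescue was analysed here. Nor do the labels say whether these libraries came from separate cultures. A difference in culture, transfection or library preparation that went with the groups cannot be told apart from a hairpin effect.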
